A study of Triticum aestivum with 9 samples.

How the data were processed

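Whole developing grains of bread wheat (Triticum aestivum), cultivar Jimai 20, were profiled on an Affymetrix wheat GeneChip, on which each transcript is read by a probe set of short oligonucleotides. The labels give 3 phases of grain filling, P1 at 11, P2 at 15 and P3 at 20 days post-anthesis, with 3 biological replicates from field plots in each, 9 arrays in all. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. Nothing in the labels ties a replicate number to a plot shared between phases, to a labelling batch or to a scan date.

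The deposited values are linear probe set signals, that is, intensity values for 61290 probe sets on each array. The submitters' processing notes name MAS5 as the tool the authors used, and its version is not given in the sources used here. MAS5 signals are computed per array and then scaled, and the deposited intensity values had a mean of 500.1 on each of the 9 arrays once 2% was trimmed at each end. The median signal lay between 71.59 and 90.38. Detection calls were not used here. No further normalization between arrays was applied, so a change reported here is relative to the bulk of the signal on its array. Precision is limited by the number of arrays, 3 per phase.

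Control probe sets were left out, 175 in all, made up of 111 Affymetrix control and 64 reporter probe sets, which left 61115. The platform annotation names 1273 of these with 1 gene symbol, 0 with several and 59842 with none. Of its 771 genes, 770 were matched by gene identifier to the RefSeq gene table of the wheat assembly IWGSC CS RefSeq v2.1, which was used for symbols and synonyms only. Many symbols are bare locus names, and an informative symbol or synonym was found for 200 probe sets of 102 genes. A probe set without a name is unnamed here, not without a gene. Wheat is hexaploid and many of the named genes belong to multigene families, so a probe set can also bind transcripts of related copies, and its signal is uncertain as a measure of a single copy.

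Changes were tested with limma 3.58.1 in R 4.3.3 on log2 of the deposited signals, with a pseudocount of 0. The lowest 40% of probe sets by mean log2 signal were left out, which leaves 36669 with a geometric mean signal above 44.8. One linear model held all 9 arrays with phase as the factor and gave 6 residual degrees of freedom. Its variances were moderated with an intensity trend (a median of 5.8 prior degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all 36669 probe sets. A probe set was called changed at an adjusted p under 0.05 and a change of at least 2-fold. The words rose, fell and changed are kept for such calls. The comparisons were P3 with P1, P2 with P1 and P3 with P2, a moderated F test over the 3 phases, and a test of whether the step from P2 to P3 differed from the step from P1 to P2. Errors of signals are standard deviations over 3 arrays, and errors of log2 changes are limma's standard errors.

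Background on each array was taken as the 95th percentile of the reporter probe sets, which stand for sequences foreign to wheat. It ranged from 89.4 to 153.3. By array it was 103.5, 89.4 and 89.5 at P1, 103.8, 153.3 and 148.2 at P2 and 111.9, 115.7 and 99.7 at P3. Raising dim signals to it thus lifts them most on P2 replicates 2 and 3. That moved the median log2 change of all probe sets to 0.243 for P2 against P1 and -0.129 for P3 against P2. List medians with dim signals at background carry that difference too. A probe set below background on all 3 arrays of a phase has only a bound there. Its change is then given as at least N-fold, from the mean log2 signal of the brighter phase against the mean of, per array, the higher of the background and the probe set's own signal.

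Themes for 25 gene lists were fixed before the data were examined, for storage proteins, starch, the cell cycle, the green pericarp, embryo and aleurone, redox enzymes and others. The fixed search patterns found only 11 members in the sparse annotation. A further 130 were assigned by hand from symbols and synonyms, after the annotation was read but before any probe set's values were looked at. In all 17 lists had a member, 115 members passed the filter on signal, and 10 lists had at least 3 tested probe sets. Those 10 were tested with camera, limma's competitive test of a list against the other probe sets, at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, limma's test of whether a list moves one way on balance, were the alternatives. Lists had few genes and several probe sets per gene, so members were not independent.

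The comparisons, the calling criteria and the rule for the genes named were fixed together with the themes. For P3 against P1 it took the 10 highest and 10 lowest log2 changes, and for each other comparison the 8 highest and 8 lowest. Only called probe sets with an informative name and no overlap between the 2 groups counted, with 1 probe set per gene. From each list it took the 3 members with the smallest p in P3 against P1 and the brightest member. Not every gene the rule took is reported.

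Other settings tried, also planned, were pseudocounts of 16 and 64, quantile and median scaling between arrays, no filter and a 60% filter on dim probe sets, no intensity trend, robust moderation, array quality weights, each pair of phases fitted alone, the replicate number as a block, an adjusted p under 0.01 or no fold requirement, 1 probe set per named gene, and leaving out each array in turn. Settings added after seeing the data were scaling to the hybridization controls or to the poly-A controls, the 3-prime to 5-prime ratio of wheat control transcripts as a covariate, raising dim signals to background, and leaving out probe sets with a mean over 30000. The script was tested on simulated data with 100 probe sets changed at each size. For P3 against P1 it recovered 22% of 2-fold and 67% of 4-fold changes with 4 false calls among 36669 probe sets. For P2 against P1 the shares were 24% and 68% with 5 false calls, and for P3 against P2 they were 20% and 71% with 3. A true 2-fold change lies at the calling threshold, and by adjusted p alone 45% of these were recovered for P3 against P1. In the data 12772 probe sets passed an adjusted p under 0.05 there, far more than were changed in the simulation. The simulated adjustment was therefore stricter, and neither the shares nor the false calls carry over to the data. In 40 simulated runs camera called the list shifted by 1 on the log2 scale in 40, and 6 of 360 unshifted lists. The simulated noise was independent between probe sets, while the correlation estimated within the real lists reached 0.75. The rate of 6 in 360 therefore does not hold for camera on the real lists. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.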

Results

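Transcript levels were measured in developing wheat grain at 11, 15 and 20 days post-anthesis (P1, P2 and P3), on 3 arrays per phase, to follow how they change as the grain fills. Signals on the 9 arrays had medians between 71.59 and 90.38 and reached 66513 to 106425 at the top. The brightest 100 probe sets held between 8.31% and 11.28% of the total signal. Arrays of the same phase correlated at r = 0.947 to 0.962 over 9 pairs, and arrays of different phases at 0.871 to 0.930 over 27 pairs, across probe sets, which are not independent replicates. The standard deviation of log2 differences was 0.609 to 0.748 within a phase and 0.837 to 1.171 between phases. In a principal component analysis the first component held 42.9% of the variance and parted P1 from both later phases, and the second held 18.5% and placed P2 at one end, P3 at the other and P1 between them.

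**Figure D1:**
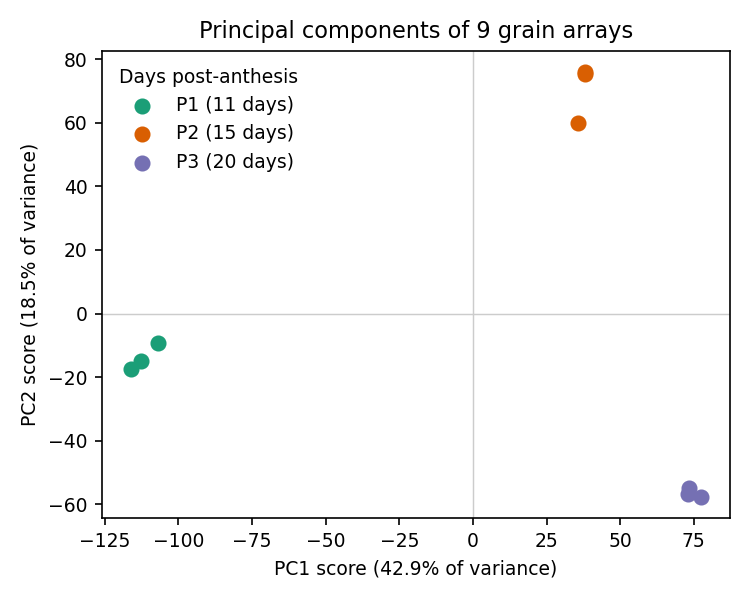
First (x axis) and second (y axis) principal component scores of log2 signals, with 1 point per array and 1 colour per phase. The P1 arrays lie at -107.0 to -116.1 on the first component, and P2 (59.8 to 76.0) and P3 (-55.0 to -57.6) lie apart on the second.

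Control transcripts spiked into the RNA before labelling set the P2 arrays apart. The mean log2 ratio of 3-prime to 5-prime signal over the 4 poly-A controls was 2.15 ± 0.11 (SD, n = 3) at P1, 1.67 ± 0.09 at P2 and 2.16 ± 0.09 at P3. P2 against the other phases gave an exact two-sided permutation p = 0.0119 (n = 3 and 6, the smallest that 84 splits allow, adjusted p = 0.0357 over 15 control measures). The ratio of thr was 3.52, 2.33 and 3.58 and that of dap 2.56, 1.90 and 2.76, while P2 was not distinguishable for lys (exact permutation p = 0.667) or phe (exact permutation p = 0.571). The poly-A controls' log2 level, relative to its mean over arrays, was -0.26 ± 0.08, 0.64 ± 0.04 and -0.38 ± 0.05. For the hybridization controls, which are added after labelling, it was -0.09 ± 0.36, -0.01 ± 0.30 and 0.10 ± 0.14 (exact permutation p = 0.929 for P2 against the rest). Among wheat transcripts with 3-prime and 5-prime probe sets, the log2 ratio of Sucsyn was 7.15 ± 0.17 at P1, 5.67 ± 0.14 at P2 and 6.51 ± 0.22 at P3. The mean of 4 such transcripts (CYP86-TA, G-6-PDH, Sucsyn and Ubiquitin) was 3.32 ± 0.24, 2.12 ± 0.09 and 2.53 ± 0.07. For P2 against the rest its exact permutation p was 0.0238 (adjusted p = 0.0595). For P3 against P1 it was 0.1, the smallest that 3 against 3 allows. Left out of it were actin (1.22, -1.14 and -0.97), ef1a (-1.6, 0.5 and -1.67) and gapdh (-2.05, -2.22 and -2.34). The 5-prime probe sets of CYP86-TA, G-6-PDH and Sucsyn averaged 192, 197 and 196, near background. The mean ratio is therefore an uncertain measure of RNA integrity. The poly-A ratios of P1 and P3 differed by less than their spread, although dap (2.56 and 2.76) and lys (1.89 and 1.75) each gave the smallest p that 3 against 3 allows, an exact permutation p = 0.1.

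**Figure D2:**
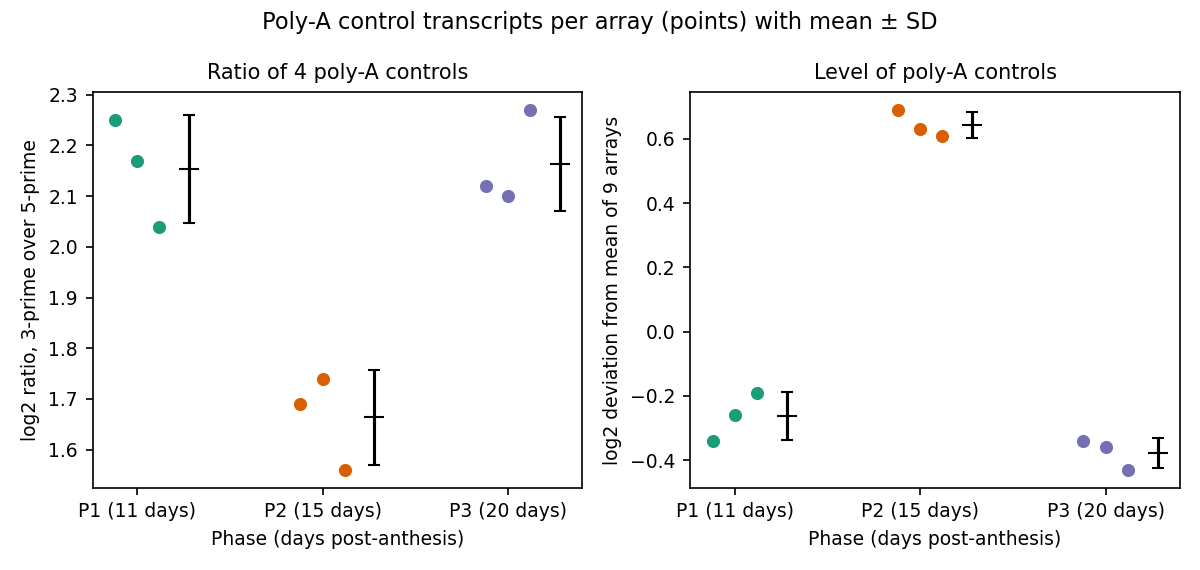
Left, the mean log2 ratio of 3-prime to 5-prime signal of 4 poly-A controls, and right, their log2 level relative to its mean over arrays, with 1 point per array by phase. The ratio averages 1.67 at P2 against 2.15 and 2.16 at P1 and P3, and the level 0.64 against -0.26 and -0.38.

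From P1 to P3 transcripts of late embryogenesis and desiccation proteins rose in all 9 tested probe sets of 4 genes. EM (LOC543497), which encodes an Em protein of maturing embryos, had a signal of 40.1 ± 9.01 (SD, n = 3) at P1, below background, and 42300 ± 3990 at P3, a rise of at least 450-fold (adjusted p = 1.84e-13). The Em gene EMH2 (LOC543480) was at 45.1 ± 41.6 and 37200 ± 5940, at least 393-fold (adjusted p = 2.11e-09). The dehydrin-type gene Rab15 (LOC543293) went from 295 ± 40.5 to 14400 ± 1040, 48.9-fold (log2 change 5.61, SE 0.10, adjusted p = 1.45e-12), and LEA1 (LOC543476) rose 2.96-fold from 5600 ± 486 to 16600 ± 1160. The list's median log2 change was 8.35, or 7.86 with dim signals at background, and its camera adjusted p was 2.34e-13 (adjusted p = 0.00213 with an estimated correlation). Adjusted over the list alone, 9 probe sets rose as well.

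Genes outside that list rose from P1 to P3 as well. WGA2 (LOC543494), wheat germ agglutinin, was below background at P1 (44.8 ± 43.4) and at 17400 ± 942 in P3, at least 185-fold higher (adjusted p = 1.14e-08). The small heat shock protein gene hsp16.9A (LOC543277) rose 21.3-fold, from 218 ± 32.1 to 4620 ± 139 (log2 change 4.41, SE 0.10, adjusted p = 8.14e-12). PEAMT1 (LOC543067), a methyltransferase of choline synthesis, rose 6.22-fold, and PIMT (LOC543193), a methyltransferase that acts on damaged proteins, rose 3.86-fold. The gene 6-FEH (LOC780575), a fructan exohydrolase, rose 3.73-fold on 1 of 3 probe sets, and with it 1 of 4 probe sets of the sucrose and sugar transport list rose and 0 fell. The tested members of that list were all of the fructan exohydrolases 6-FEH and 1-FEH (LOC543441), so no sugar transporter was tested. That list's median log2 change was 0.56 (0.55 with dim signals at background) and its adjusted p 0.121, or 0.0277 without P3 replicate 3. By the rule that selected them, all 3 arrays of 1 phase lay above all 3 of the other in every gene named here for a highest or lowest change.

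Of 12 probe sets of amylase and protease inhibitors, 5 rose from P1 to P3, 0 fell and 7 did not pass. Those that rose were of 3 serpin genes, which block proteases, and of a xylanase inhibitor gene. The amylase inhibitors and 2 probe sets of another serpin, WSZ1b (LOC100037548, log2 changes 0.58 and 0.57), did not pass. Serpin-Z1C (LOC542985) rose 6.60-fold, from 1980 ± 91.6 to 13100 ± 1470 (log2 change 2.72, SE 0.15, adjusted p = 2.14e-08). Serpin-Z2A (LOC543376) rose 5.95-fold, Serpin-Z2B (LOC543382) 5.17-fold and the xylanase inhibitor gene XIP-I (LOC542997) 4.64-fold, to 45300 ± 8140. The brightest inhibitor, ATI (LOC543286), was at 55300 ± 5600 and 61400 ± 11100. The list's median log2 change was 0.58 and its adjusted p 1.46e-05 (adjusted p = 0.22 with an estimated correlation). Among 6 probe sets in the list for puroindolines and thionins, all of them for thionins, small antimicrobial proteins of the endosperm, 2 rose and 0 fell. TTHV rose 3.66-fold, from 13500 ± 275 to 49900 ± 6790 (adjusted p = 6.71e-09). Pur-A1 (LOC543413) rose 2.13-fold on 1 of 2 probe sets (log2 change 1.09, SE 0.10), and its log2 change was 0.91 under quantile normalization, 0.92 under median scaling, 0.89 under scaling to the hybridization controls, 0.63 with the wheat 3-prime to 5-prime ratio as a covariate and 0.97 without P3 replicate 3, which ends the call. THI1.2, with a log2 change of 0.96, was not called. It was called without P1 replicate 2 (1.04), without P3 replicate 1 (1.02) or 2 (1.04) and under scaling to the poly-A controls (1.07), and was at 0.22 with the covariate. The median of the list was 0.85 and its adjusted p 0.000684 (adjusted p = 0.23 with an estimated correlation, and 0.107 with the ratio as a covariate).

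Photosynthesis transcripts, which mark the green pericarp layer, fell from P1 to P3 in 6 of 15 probe sets and rose in 0, or fell in 7 adjusted over the list alone. PsbO (LOC543291) and PsbP (LOC543290), proteins of the oxygen-evolving complex of photosystem II, fell 4.86-fold and 3.72-fold. PsbO went from 8290 ± 800 to 1700 ± 128 (log2 change -2.28, SE 0.09, adjusted p = 6.54e-10), and PRK (LOC543283), phosphoribulokinase of the Calvin cycle, fell 2.64-fold from 3760 ± 150 to 1420 ± 11.6. None of the 9 rubisco (rbcl, LOC100049018) probe sets was called, and the brightest was at 60200 ± 3150 and 43300 ± 2830 (log2 change -0.48). The list's median log2 change was -0.99, or -0.89 with dim signals at background, and its adjusted p 4.4e-07 (adjusted p = 0.00623 with an estimated correlation).

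Antioxidant enzyme transcripts fell in 2 of 6 probe sets. The 6 belong to CAT1, Trx-M and GSTZ1 (LOC543412), so the list speaks for these genes only. PER1 (LOC543108, synonym peroxidase) was not assigned to it and went the other way, from 23300 ± 1940 to 38600 ± 7440 (log2 change 0.71, adjusted p = 0.000319 by limma, not called). Prx1, given below, was outside the list too and fell. Catalase, CAT1, fell 2.41-fold from 818 ± 92.5 to 341 ± 50.8, and Trx-M (LOC542973), a thioredoxin of plastids, fell 2.30-fold. The list's median log2 change was -0.79 and its adjusted p 0.0035 (adjusted p = 0.0614 with an estimated correlation). A dim probe set of CAT1 was below background in each phase. The beta-amylase gene BMY1 (LOC543318) fell 15.8-fold, from 2730 ± 82.5 to 176 ± 37.3 (log2 change -3.98, SE 0.15, adjusted p = 6.34e-10). XTH, a cell wall xyloglucan enzyme, fell 2.73-fold, Prx1 (LOC606328) 2.58-fold on the brightest of 4 probe sets, 3 of which were called, Glc1 (LOC543469) 2.60-fold and wci (LOC542996) 2.56-fold. On 1 of 2 probe sets lgul (LOC542984) fell at least 2.33-fold, from 255 ± 32.2 to 72.7 ± 20.0, below background there (adjusted p = 0.000534), while the brighter one was at 357 and 212 (log2 change -0.75) and was not called. With the ratio as a covariate the calls of Glc1, XTH, lgul and a dimmer Prx1 probe set ended as standard errors widened, with log2 changes of -2.14 (SE 0.71, before -1.87, SE 0.25) for that Prx1 probe set, below background on 1 of 3 P3 arrays, -1.44 (SE 0.42, before -1.38, SE 0.15) for Glc1 and -1.20 (SE 0.43, before -1.45, SE 0.15) for XTH. For lgul the fitted value, which is no bound, was -2.13 (SE 0.90, before -1.84, SE 0.31).

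Genes for gliadins and glutenins, the main storage proteins, were among the bright transcripts in both phases, and 16 of 17 probe sets did not pass both criteria, though 8 of the 17, the 1 called among them, had an unadjusted p under 0.05 by limma. The list also held probe sets of the avenin-like genes LOC100125692 and LOC780582. The smallest p in the list was that of 1 of 4 probe sets of an avenin-like b gene (LOC100125692), at 21400 ± 1660 and 11100 ± 431 (log2 change -0.94, SE 0.07, adjusted p = 3.39e-07). It passed 2-fold under quantile normalization (-1.03), median scaling (-1.12), scaling to the hybridization controls (-1.14) and with the wheat 3-prime to 5-prime ratio as a covariate (-1.02). The brightest, an alpha-gliadin (LOC543210), was at 59200 ± 4750 in P1 and 66100 ± 17700 in P3. A dim probe set of low-molecular-weight glutenin (LOC543213) fell at least 1.18-fold, from 137 ± 60.3 to 52.9 ± 29.3 (adjusted p = 0.0422), and 14 alternatives ended that call, among them leaving out each of P1 replicate 2, P1 replicate 3, each P2 array and P3 replicate 3. A brighter probe set of that gene was at 31500 ± 834 and 40600 ± 3800. The list's median log2 change was 0.08, its mean -0.01 and its adjusted p 0.791, upward here and downward under quantile normalization (adjusted p = 0.174) and median scaling (adjusted p = 0.658). Among the 226 probe sets with a mean signal over 30000, the median absolute log2 change was 0.21 and 8.4% were called, against 0.35 and 17.1% for 954 probe sets between 10000 and 30000. In starch synthesis 1 of 4 probe sets fell: AGA.1 (LOC543278), a subunit of ADP-glucose pyrophosphorylase, 2.24-fold on its brighter probe set (log2 change -1.16, and -0.84 with the ratio as a covariate, which ended the call). The small subunit AGP-S (LOC543299) was at 42000 ± 1890 and 32800 ± 1620, and granule-bound starch synthase GBSS-I (LOC543395) at 13100 ± 307 and 11600 ± 836. The starch list's median log2 change was -0.27 and its adjusted p 0.0598, or 0.0453 without P1 replicate 2, 0.0277 without P3 replicate 3, 0.0301 under quantile normalization, 0.022 with no filter and 0.02 with 1 probe set per gene.

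Of 18 histone probe sets 0 were called, with wcH2B-8 (LOC543184) at 1890 ± 159 and 3170 ± 83.5 and wcH2A-9 (LOC732714) at 1960 ± 278 and 1020 ± 140. The log2 change of that wcH2A-9 probe set was -0.95, and it was called under median scaling (-1.12), under scaling to the hybridization controls (-1.15), without P1 replicate 2 (-1.07) and without P3 replicate 3 (-1.05). The histone list's median log2 change was -0.12 and its mean 0.01, opposite in sign (adjusted p = 0.881). The list for tubulins and actins held tubulin and profilin (LOC543315) probe sets and no actin. Of its 12 probe sets 0 were called, with tubb1 (LOC543257) at 10500 ± 344 and 17900 ± 766 and tubb3 (LOC543473) at 17200 ± 618 and 10300 ± 789 (list median 0.30, adjusted p = 0.434). By limma 10 of the histone and 9 of the tubulin and profilin probe sets had an unadjusted p under 0.05, and fry gave these lists adjusted p = 0.282 and 0.0451. The 7 lists under the minimum size held 1 or 2 tested probe sets each. Of these, the amylase (BMY1), cell wall (XTH) and heat shock (hsp16.9A) lists had a call, and the abscisic acid and gibberellin, glycolysis, lipid transfer and ribosomal lists had 0 calls in any comparison.

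Over all 36669 probe sets tested, 3067 rose and 1746 fell from P1 to P3, 13.1% in all, among them 1090 and 547 at 4-fold or more. Phases did not overlap in 17501 probe sets (47.7%, against 10% by chance). Rises made up 63.7% of the calls, or 48.0% under median scaling and 45.8% under scaling to the hybridization controls. These scalings moved the median log2 change of all probe sets, 0.067 as deposited, to -0.107 and -0.13, so changes are relative to that middle. With the ratio as a covariate 2147 probe sets were called, and 4790 without the P2 arrays. In all 5 of 10 lists shifted, 2 with an estimated correlation and 8 with fry.

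**Figure D3:**
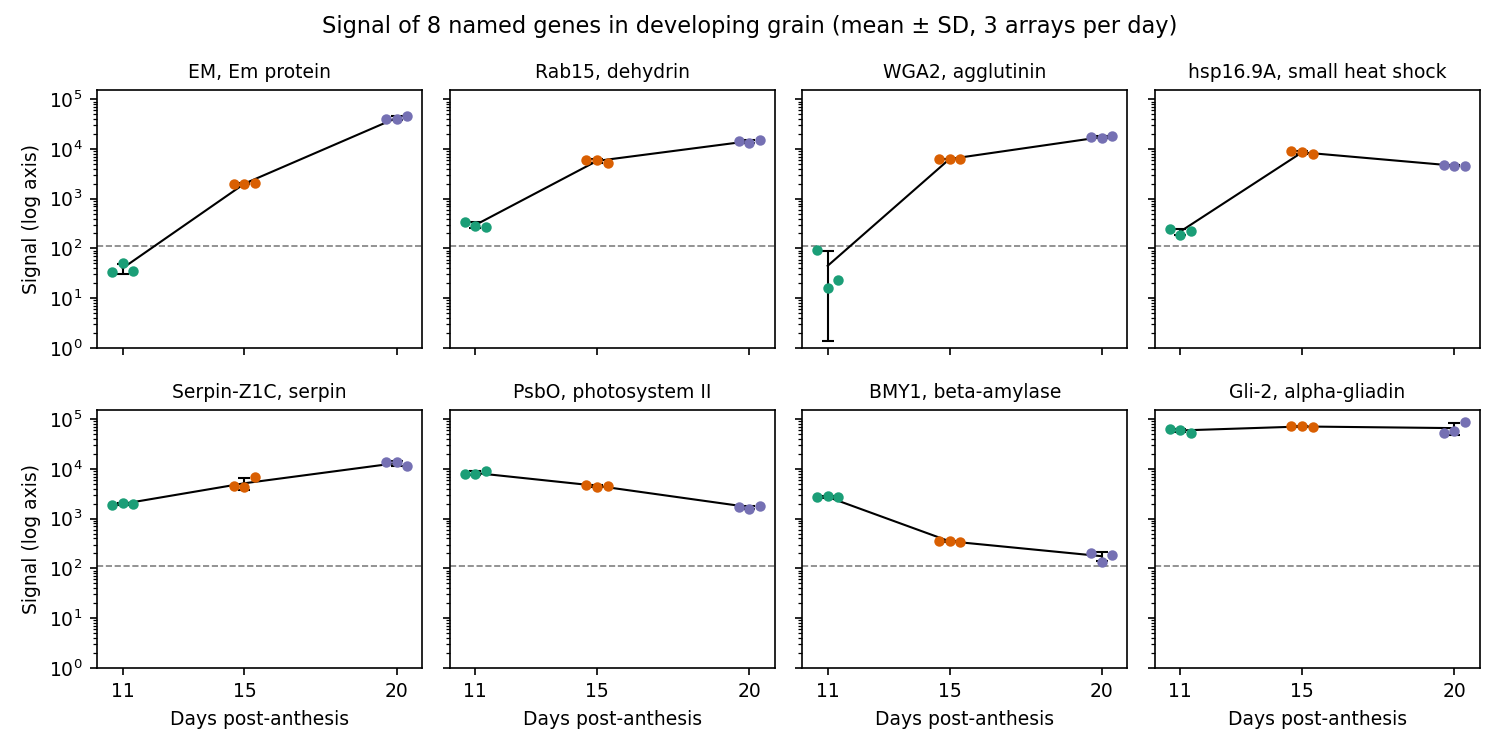
Signal (log axis) against days post-anthesis for EM, Rab15, WGA2, hsp16.9A, Serpin-Z1C, PsbO, BMY1 and an alpha-gliadin, with points for arrays, black lines for the mean ± SD (n = 3) and a dashed grey line for background. EM goes from 40.1 to 2010 and 42300, and BMY1 from 2730 to 350 and 176.

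**Figure D4:**
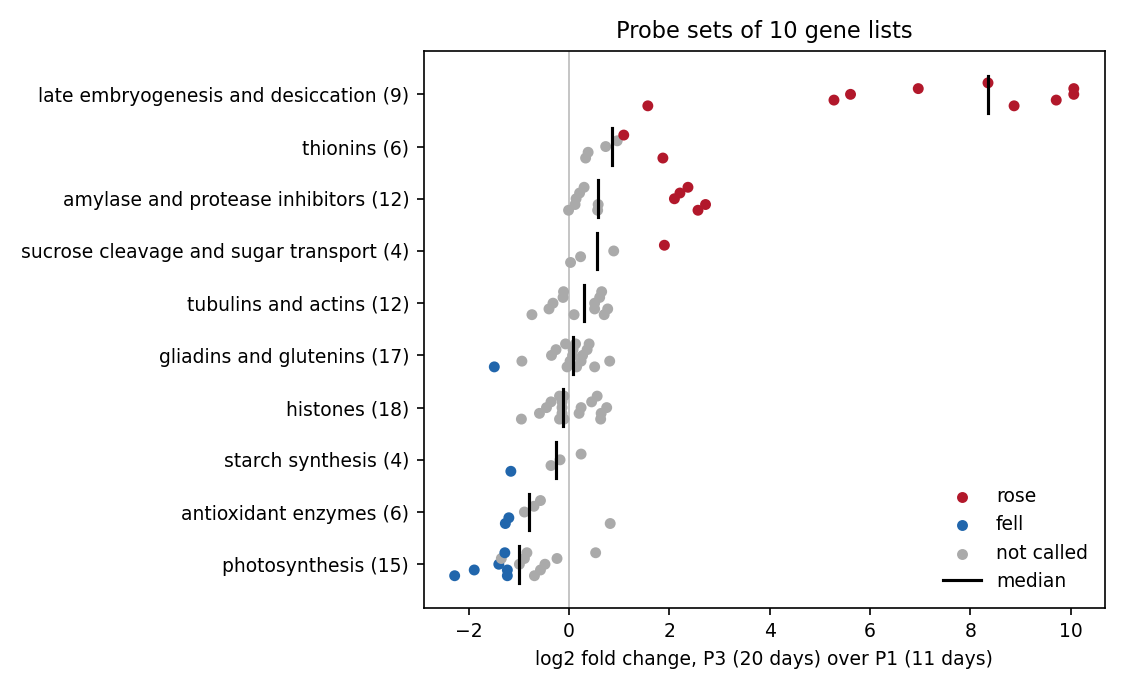
Log2 change from P1 to P3 (P3 over P1) of each tested probe set in 10 gene lists, red where it rose, blue where it fell and grey where it was not called, with a black bar at the list median. The medians are 8.35 for late embryogenesis and -0.99 for photosynthesis, while that of gliadins and glutenins, 0.08, belongs to a list that turned downward under quantile normalization and median scaling.

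From P1 to P2 the same late embryogenesis list rose in 9 of 9 probe sets, and hsp16.9A rose 39.5-fold, from 218 ± 32.1 to 8570 ± 454 (log2 change 5.30, SE 0.10, adjusted p = 5.04e-12). WGA2 rose at least 66.9-fold, from 44.8 ± 43.4 to 6280 ± 55.2 (adjusted p = 9.28e-08). EM rose at least 21.4-fold, to 2010 ± 27.9 (adjusted p = 1.81e-11), EMH2 at least 23.9-fold, to 2250 ± 117 (adjusted p = 4.2e-07), and Rab15 19.6-fold, to 5760 ± 408. BMY1 fell 7.78-fold, from 2730 ± 82.5 to 350 ± 12 (log2 change -2.96, SE 0.15, adjusted p = 1.73e-08). The P2 arrays are those whose poly-A ratio was 1.67 against 2.15 at P1. The late embryogenesis list had a median log2 change of 4.58, or 4.11 with dim signals at background, and an adjusted p of 6.41e-12 (adjusted p = 0.00296 with an estimated correlation).

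Among the other genes, PEAMT1 rose 7.25-fold, PIMT 4.53-fold and 6-FEH 3.73-fold from P1 to P2. In the sucrose and sugar transport list, of which only fructan exohydrolases were tested, 2 of 4 probe sets rose, both of 6-FEH (median log2 change 1.34, or 1.12 with dim signals at background, adjusted p = 0.0794). That list's adjusted p was 0.0487 under median scaling, 0.0266 and 0.0119 under scaling to the hybridization and poly-A controls, and 0.0468 without P1 replicate 2. Inhibitors rose in 4 of 12 probe sets, led by Serpin-Z2B at 3.54-fold and Serpin-Z1C at 2.55-fold (median 0.36, adjusted p = 0.000708, adjusted p = 0.303 with an estimated correlation). Thionins rose in 1 of 6, TTHV at 2.28-fold (median 0.40, adjusted p = 0.00589, adjusted p = 0.303 with an estimated correlation), and this list's direction turned downward with the ratio as a covariate (adjusted p = 0.823). The tubulin list shifted upward with 0 of 12 calls (median 0.35, adjusted p = 0.000693, adjusted p = 0.252 with an estimated correlation). Under scaling to the poly-A controls, which moves all P2 signals together, it did not shift and its direction was downward (adjusted p = 0.535). By limma 9 of its probe sets had an unadjusted p under 0.05, and tubb1 was at 10500 ± 344 and 20600 ± 982.

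Some storage protein genes fell from P1 to P2. An avenin-like b gene (LOC100125692) fell 4.14-fold on 1 of 4 probe sets (log2 changes -0.68, -0.59 and 0.16 on the others), from 21400 ± 1660 to 5160 ± 46.4 (log2 change -2.05, SE 0.07, adjusted p = 3.94e-10), and the avenin-like a gene avnla (LOC780582) fell 2.26-fold on 1 of 2 probe sets, from 38200 ± 2790 to 16900 ± 445 (log2 change -0.95 on the other). They were the 2 of 17 probe sets in the gliadin and glutenin list that fell, and 0 rose (median -0.36, or -0.28 with dim signals at background, adjusted p = 0.0118, adjusted p = 0.324 with an estimated correlation and 0.4 with 1 probe set per gene). Both are avenin-like, and no probe set of the list's other genes was called. Histones fell in 1 of 18, wcH2A-2 (LOC732712) at 2.33-fold with 1 of 3 P2 arrays below background, whose log2 change was -0.95 without P2 replicate 2 and -0.88 with the ratio as a covariate, each ending the call. The histone list's median was -0.34 (adjusted p = 0.00119, adjusted p = 0.209 with an estimated correlation). Prx1 fell 2.67-fold on its brightest probe set (920 ± 103 to 344 ± 31.9), wci 2.98-fold, DMAS1 (LOC100037594), which makes an iron-binding phytosiderophore, 2.27-fold on 1 of 3 probe sets (1.93-fold and 1.37-fold lower on the others, not called). On 1 of 2 probe sets lgul fell at least 1.90-fold (255 ± 32.2 to 77.3 ± 13.4, adjusted p = 0.000959), a call that ended with dim signals at background (-0.93), and the other was at 357 and 180 (log2 change -0.99, not called). In photosynthesis 1 of 15 rose and 1 fell, a rubisco probe set at 2.29-fold and FBP at 2.11-fold, both chosen after their values were seen (median -0.10, or 0.09 with dim signals at background, adjusted p = 0.195, and 0.00249 with 1 probe set per gene). Antioxidant enzymes (median -0.51, or -0.22 with dim signals at background, adjusted p = 0.0794, and 0.0329 with no filter) and starch synthesis (median 0.03, test downward, adjusted p = 0.715) had 0 calls by limma, with 3 of 6 and 2 of 4 probe sets at an unadjusted p under 0.05.

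In all 2528 probe sets rose and 2124 fell from P1 to P2, 12.7% of those tested, with 789 and 471 at 4-fold or more. Phases did not overlap in 16920 (46.1%, against 10% by chance). The rising share was 54.3%, or 42.5% under median scaling, 4.9% under scaling to the poly-A controls and 71.8% with the ratio as a covariate. The count was 560 with that covariate, 14983 under scaling to the poly-A controls and 2887 with a pseudocount of 64. That covariate raised the median standard error from 0.23 to 0.95 and ended the calls named above for WGA2, EMH2, PIMT, 6-FEH, avnla, DMAS1 and lgul and that of a dimmer Prx1 probe set. Log2 changes with it were 1.97 (SE 0.60, before 1.90, SE 0.14) for 6-FEH, -1.51 (SE 0.36, before -1.18, SE 0.09) for avnla, -2.38 (SE 1.05, before -1.96, SE 0.25) for that Prx1 probe set, below background on 2 of 3 P2 arrays, 1.81 (SE 0.75, before 2.18, SE 0.18) for PIMT and -0.66 (SE 0.48, before -1.18, SE 0.12) for DMAS1. Against a phase below background the fitted values, which are no bounds, were 5.32 (SE 1.78, before 7.57, SE 0.46) for WGA2, 3.03 (SE 1.53, before 6.02, SE 0.43) for EMH2 and -2.18 (SE 1.32, before -1.73, SE 0.31) for lgul. In all 6 of 10 lists shifted, 1 with an estimated correlation and 9 with fry. Other settings also ended list calls: the covariate for inhibitors (adjusted p = 0.147), histones (0.09) and tubulins (0.202), scaling to the hybridization controls for tubulins (0.0833) and thionins (0.087), and scaling to the poly-A controls for inhibitors (0.0882) and thionins (0.535).

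From P2 to P3 the Em genes rose further, and photosynthesis transcripts fell. EM went from 2010 ± 27.9 to 42300 ± 3990, 21.0-fold (log2 change 4.39, SE 0.13, adjusted p = 5.99e-10), and EMH2 rose 28.6-fold on 1 probe set and 16.4-fold on another. Rab15 rose 2.50-fold, from 5760 ± 408 to 14400 ± 1040, and 2.66-fold on a dimmer probe set (log2 change 1.41, SE 0.25, and 0.51, SE 0.28, with the ratio as a covariate, which ended that call). LEA1 was at 13500 ± 2040 and 16600 ± 1160 (adjusted p = 0.0503). PsbO fell 2.68-fold, from 4570 ± 265 to 1700 ± 128 (log2 change -1.42, SE 0.09, adjusted p = 2.08e-07), and PsbP 2.69-fold, from 6470 ± 706 to 2400 ± 146. The poly-A ratio was 1.67 on these P2 arrays and 2.16 at P3. Late embryogenesis rose in 8 of 9 probe sets (median 4.04, adjusted p = 1.52e-09, adjusted p = 0.00353 with an estimated correlation). Photosynthesis fell in 7 of 15, or in 8 adjusted over the list alone (median -1.02, or -0.71 with dim signals at background, adjusted p = 1.27e-08, adjusted p = 0.00353 with an estimated correlation).

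Serpin-Z2A rose 3.43-fold from P2 to P3 and Serpin-Z1C 2.59-fold, the 2 of 12 inhibitor probe sets that rose (median 0.22, adjusted p = 0.000448, adjusted p = 0.219 with an estimated correlation). The avenin-like b gene rose 2.15-fold on that probe set, from 5160 ± 46.4 to 11100 ± 431 (adjusted p = 2.44e-07). The gliadin Gli-B2-11 (LOC543385) rose 2.24-fold, or by 0.93 on the log2 scale without P2 replicate 1 and 0.55 with the ratio as a covariate, each ending the call. They were the 2 of 17 probe sets in the gliadin and glutenin list that rose, and 0 fell (median 0.50, adjusted p = 0.000194, adjusted p = 0.219 with an estimated correlation). Histones rose in 1 of 18, wcH2A-2 at 2.16-fold (median 0.41, adjusted p = 5.56e-06, adjusted p = 0.0408 with an estimated correlation). WGA2 rose 2.77-fold (log2 change 1.47, SE 0.46, adjusted p = 0.0325), a call that ended when any 1 P2 or P3 array was left out, with log2 changes that stayed between 1.43 and 1.51. Its arrays lay at 6220 to 6320 in P2 and 16400 to 18300 in P3. The SE comes from the model of all 3 phases, and the P1 arrays scattered below background (94.8, 16.3 and 23.3). The thionin list shifted upward with 0 of 6 calls and 4 unadjusted p under 0.05 by limma (median 0.45, adjusted p = 0.0156, adjusted p = 0.325 with an estimated correlation, and 0.0559 without P3 replicate 3).

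TUBA, an alpha-tubulin, fell 2.27-fold from P2 to P3 on 1 of 2 probe sets, from 4470 ± 277 to 1970 ± 52.7 (the brighter one was at 40100 ± 1720 and 37600 ± 5580), the 1 of 12 tubulin and profilin probe sets called. That list shifted downward (median -0.16, adjusted p = 0.0112, adjusted p = 0.247 with an estimated correlation). Under scaling to the poly-A controls it did not shift and its direction was upward (adjusted p = 0.221). BMY1 fell 2.03-fold, with a log2 change of -1.02 that was -0.83 without P3 replicate 2, -0.96 and -0.80 with pseudocounts of 16 and 64 and -0.86 with the covariate, each ending the call. Scaling to the poly-A controls, which moved the median log2 change of all probe sets to 1.081, left PsbO at -0.41, TUBA at -0.17 and BMY1 at -0.01. Starch synthesis shifted downward with 0 of 4 calls and 3 unadjusted p under 0.05 by limma (median -0.46, or -0.34 with dim signals at background, adjusted p = 0.0156, adjusted p = 0.139 with an estimated correlation). Antioxidant enzymes shifted downward too (median -0.56, adjusted p = 0.0156, adjusted p = 0.106 with an estimated correlation), with 0 calls downward. The 1 upward call was the dim CAT1 probe set, below background in P2 and P3, and a dim rubisco probe set called downward was likewise below it in both. The sucrose and sugar transport list, in which only fructan exohydrolases were tested, had 0 of 4 calls and 2 unadjusted p under 0.05 by limma (median -0.36, or -0.14 with dim signals at background, adjusted p = 0.525).

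In all 1634 probe sets rose and 1016 fell from P2 to P3, 7.2% of those tested, with 233 and 236 at 4-fold or more. Phases did not overlap in 14769 (40.3%, against 10% by chance). The rising share was 61.7%, or 46.5% under scaling to the hybridization controls and 99% under scaling to the poly-A controls. The count was 19163 under the latter, 1651 with the ratio as a covariate and 1623 with a pseudocount of 64. In all 9 of 10 lists shifted, 3 with an estimated correlation and 5 under scaling to the hybridization controls. That scaling ended the calls of antioxidant enzymes (adjusted p = 0.0904), thionins (0.135), starch synthesis (0.128) and tubulins (0.0503). Scaling to the poly-A controls ended those of antioxidant enzymes (0.601) and starch synthesis (0.906), and the covariate (0.0633) and dim signals at background (0.0506) that of tubulins.

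Across the 3 phases, 250 probe sets rose in both steps, among them EM, EMH2, Rab15, WGA2 and Serpin-Z1C, and 127 fell in both, among them BMY1. A further 528 fell and then rose, such as the avenin-like b gene (21400, 5160 and 11100) and wcH2A-2 (478, 212 and 451), and 301 rose and then fell. The balance of these turned round with a pseudocount of 64 (154 and 224), with dim signals at background (170 and 282) and with the ratio as a covariate (24 and 95), and was 9813 and 46 under scaling to the poly-A controls. Background was highest on P2 replicates 2 and 3 (153.3 and 148.2), so raising dim signals to it by itself favours a rise and then a fall. Independent lists of the same sizes would share 112.6, 58.9, 94.6 and 70. In 20 simulations without an effect the highest count was 0 for each. Without an effect few calls can arise in either step, so these simulations do not test the excess over independent lists. Part of the excess can come from the P2 arrays, which both steps share. Called in the first step alone were 1977 probe sets that rose, that of hsp16.9A among them, and 1469 that fell, and in the second step alone 856 and 588. For hsp16.9A the second step differed from the first by -6.19 on the log2 scale (SE 0.18, adjusted p = 3.28e-10). The steps differed in 10166 probe sets (27.7%), 5610 with the second step higher and 4556 with it lower. That count was 3609 under scaling to the hybridization controls, 27505 under scaling to the poly-A controls and 357 with the ratio as a covariate. The F test over the phases passed in 16565 probe sets (45.2%), and in 8959, 28331 and 8855 under those same settings.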

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

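The values here were looked for only after the data were seen. A reporter probe set, meant for a sequence foreign to wheat and outside the comparisons, had a mean signal of 50100 over the 9 arrays (41700 to 58200), while the other 63 reporter probe sets had a median of 21.9 and a highest mean of 166. The Cre hybridization control had a mean signal of 43100, and across the 9 arrays the pair gave Pearson's r = 0.58 (exact permutation p = 0.107) and Spearman's rho = 0.58 (exact permutation p = 0.108), and r = 0.47 without the 2 arrays farthest from the median.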

How the results depend on the processing

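Scaling to hybridization or poly-A controls, the covariate, raising dim signals to background and leaving out bright probe sets were chosen only after the data were seen. Across all alternatives, 191 counts stayed within 1.5 times the reported count and 25 did not. For lists, 781 results kept direction and side of the threshold, 18 passed it newly, 32 no longer passed and 3 reversed. For named probe sets these numbers were 1944, 13, 75 and 1. Leaving out 1 array gave 4287 to 4641 calls for P2 against P1, 2333 to 2698 for P3 against P2, 4555 to 4833 for P3 against P1, 14786 to 16002 for the F test and 8235 to 9990 for the difference of steps, and 6 to 7, 8 to 9 and 5 to 7 shifted lists. Replicate numbers as a block gave 4574, 2597 and 4773 calls, although same-number arrays correlated no better (median r = -0.004) than others (0.005).

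In the order P2 against P1, P3 against P2 and P3 against P1, calls without a fold requirement were 12485, 9527 and 12772, as the looser criterion implies. With 1 probe set per named gene, 678 in all, they were 102, 79 and 152 because fewer were tested. These are larger shares than the 12.7%, 7.2% and 13.1% called over all probe sets. A pseudocount of 64, which shrinks changes of dim probe sets, gave 2887 and 1623 for the first pair of comparisons. Camera with an estimated correlation shifted 1, 3 and 2 lists, and fry 8 for P3 against P1, since it does not compare a list with other probe sets. Scaling to the hybridization controls gave 5 lists for P3 against P2, 8959 probe sets by the F test and 3609 for the difference of steps (the cause was not tested). Scaling to the poly-A controls gave 14983 and 19163 calls for the first pair of comparisons, 28331 by the F test and 27505 for the difference of steps, because it moves all P2 signals together. It reversed the direction of the tubulin list in P2 against P1 (adjusted p = 0.535) and P3 against P2 (0.221), where neither reversed result passed the threshold. The wheat ratio as a covariate gave 560, 1651 and 2147 calls, 2 lists for P2 against P1, 8855 by the F test and 357 for the difference of steps, and reversed the thionin list in P2 against P1 (0.823). That ratio spreads by 0.15 within phases and 0.61 between them, and the covariate raised median standard errors from 0.23 to 0.95, 0.40 and 0.64. Raising dim signals to background gave a dim CAT1 probe set -0.29 in P3 against P2, counted above as reversed. It was below background in both phases, so -0.29 is only the difference between the arrays' background levels. A dim rubisco probe set, likewise below background in both, had the same -0.29. A phase below background (89.4 to 153.3 by array) on all 3 arrays gives only a bound.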

Other observations

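The tests of RNA integrity, of background at P1 and of a tissue share were chosen only after the results were seen, as were the genes of this paragraph. From P1 to P3 the malate transporter gene ALMT1 (LOC543388) rose, from a signal of 85.7 ± 13.7 (SD, n = 3), near background, to 223 ± 8.89 (adjusted p = 0.000379), with 230 ± 25.1 at P2. From P1 to P2 the gene AdSS (LOC543243), adenylosuccinate synthetase of purine synthesis, fell 2.06-fold, from 5610 ± 301 to 2730 ± 132, and was at 3840 ± 220 in P3. The calcium channel gene TPC1 (LOC543074) was at 248 ± 33.0, 149 ± 25.5 and 303 ± 18.4 and rose 2.05-fold from P2 to P3 (adjusted p = 0.00222).

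More probe sets turned at P2 (829) than moved the same way in both steps (377). Between 666 and 9859 turned under 4 other scalings, the highest with the poly-A controls. The number thus depends on scaling, but no scaling run removed the excess over the same way. At most 22 turned in 20 simulations with P2 midway, which argues against chance scatter that is independent between probe sets. A deviation shared by many probe sets of the P2 arrays could not arise in those simulations and is not addressed by them. With a pseudocount of 64, 378 turned and 279 moved the same way, and with dim signals at background 452 and 322, so dim probe sets hold part of the number. The latter pair also carries the higher background of P2 replicates 2 and 3. A labelling reaction that differed at P2 is a candidate explanation, since the poly-A controls' mean log2 ratio there, 1.67, lay outside the range of the other arrays. With the wheat 3-prime to 5-prime ratio as a covariate 119 turned, but the ratio varies by 0.15 within phases against 0.61 between them, so RNA integrity and phase cannot be told apart, and development stays open, untested.

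Of 17 probe sets in the gliadin and glutenin list, avenin-like genes included, 16 did not pass both criteria between P1 and P3 (median log2 change 0.08, over members that went both ways). Signals near the top of the measured range could hide changes: in 10 genes with a probe set over 30000, the absolute log2 change was lower there than in dimmer probe sets of the same gene (median difference -0.18, lower in 7 and tied in 1, exact two-sided sign test p = 0.18). In 25 control genes the difference was -0.02, lower in 13 (permutation p = 0.327 between the sets). Saturation and small true changes cannot be told apart from these few genes, and development stays untested here as well.

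Late embryogenesis probe sets rose from P1 to P3. At P1, 4 of the 9 were below background on all 3 arrays. With dim signals raised to background, 9 of 9 still rose at least 2-fold, between 2.96-fold (LEA1, far above background at P1) and 450-fold. Background at P1 is thus not the whole cause. As the P3 signals lay far above background, the raising could hardly have ended the rise. If a growing share of 1 tissue with constant levels were the whole cause, and both genes were expressed there alone, Em and Rab15 would move together in the second step. The 5 Em probe sets exceeded the 3 of Rab15 by 3.16 (SE 0.10) on the log2 scale. Where the genes were expressed was not measured. At P1 Rab15 was at 295 ± 40.5 on 1 probe set, above background, and at 50.2 ± 24.8 on another, below it. Shares of more than 1 tissue that change unequally thus stay open. A difference in regulation between these genes may contribute, as a hypothesis from the same data, and sharing of signal between related Em copies was not tested.

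Other groupings of the 6 arrays in each comparison of phases number 10 with the real one, too few for a share under 0.05. Fitted on those 6 arrays alone, P2 against P1 gave 4402 calls (highest other 0), P3 against P2 gave 2562 (highest other 0) and P3 against P1 gave 4790 (highest other 0), so that 1 split reached the real count in each. For shifted lists the real numbers were 6 (highest other 5), 9 (highest other 6) and 5 (highest other 5), reached by 1, 1 and 3 splits. For the F test 1 of 100 drawn splits, the real one, reached 16565 (highest other 5776). For the difference of steps 1 of 100 reached 10166 (highest other 8201). The draws came from 280 and 840 possible splits, and for the difference of steps none had P1 or P3 as the middle phase. Each share is under 0.05, which argues against a chance split of the arrays. It does not part development from the difference of the poly-A controls at P2.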
